A study of Mus musculus with 8 samples.

How the data were processed

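Single-cell RNA was measured with the 10x Genomics droplet assay in mouse natural killer (NK) cell preparations. The labels list 8 samples. There were 3 spleen samples, 4 tumor samples and 1 sample of NK cells in culture before injection (day 0). NK cells from spleens of C57BL/6J mice were expanded in culture and given into a tail vein of mice that carried B16F10 melanoma or E0771 breast carcinoma, both mouse tumor lines. Per the series' design text, 1 mouse of each tumor model was taken at day 7 and at day 15, so 4 mice gave the 7 in vivo samples, and the labels list both tissues for 3 of them. How NK cells were enriched from the tissues is not given in the sources used here.

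The deposited matrix holds UMI counts, that is whole-number counts of distinct mRNA molecules per gene and barcode. The deposited gene and barcode tables hold other text fields, used as names only. Per the file headers the counts were made with Cell Ranger 6.0.1, and the submitters' processing notes name the same version and the genome mm10. The aligner settings and the annotation release are not given in the sources used here. The matrix is unfiltered: it lists 32285 genes and 16229539 barcodes, of which 6629529 have 0 UMIs, and it was deposited without cell calling or normalization. Each barcode ends in a suffix from 1 to 13, so 13 libraries were joined. No file or label used here ties a suffix to a sample, and 13 libraries cannot be matched one to one with 8 samples. No library was therefore given a tissue, day or tumor model, and none was guessed from its contents. In what follows, a library is named by its suffix only. Whether 2 libraries come from the same animal, and whether some belong to samples not analysed here, is not known. The labels also do not separate injected NK cells from NK cells of the host. The extraction text of the labels describes RNA of AAVS1-KO and CALHM2-KO (knockout) primary NK cells as well, and whether any library holds such cells is not known.

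The comparisons fixed before the data were examined were tumor against spleen, day 15 against day 7, B16F10 against E0771, in vivo against culture, and the gene list tests for these. None could be made without that map. The plan for this case, also fixed before the data were examined, was to give every result per unlabelled library, with the range and median and no test. The pooled matrix counts as 1 sample, so there are no replicates and no p-values. Shares carry 95% exact binomial (Clopper-Pearson) intervals and summed counts 95% exact Poisson intervals. Both cover counting error only. For a count of 0, the upper limit is set at 3 counts.

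Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. This left 99414 barcodes. Doublets were scored per library with Scrublet (scanpy 1.11.5). Its automatic threshold marked under 0.5% of cells in every library except libraries 5, 6 and 11, and was therefore not used. In its place, the highest-scoring barcodes were removed at a rate of 0.8% per 1000 barcodes of the library, chosen after seeing the data, which took out 8358 barcodes and left 91056 cells. Counts were scaled to 10000 per cell and log-transformed. The cells were clustered on 2000 variable genes and 30 principal components with 15 neighbours and Leiden resolution 1, without batch integration, which gave 38 clusters. Python 3.11.15, scipy 1.17.1, scikit-learn 1.9.0 and igraph 0.11.9 were used.

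Clusters were named from 16 cell type and 7 NK state marker lists fixed before the data were examined. The scoring thresholds were set after seeing the clusters. A marker counted as present at 50 CPM or more and at 20% or more of its highest cluster. The candidate class was the one with most markers among the 15 genes of highest fold or, without a clear lead, with the largest share of its markers present. A name then needed at least 3 present markers and 1 in 3 of its list, no close runner-up class where the share decided, no other class with more of the 10 leading genes, no low UMI count without leading markers, and the same name at Leiden resolution 2 for most of its cells. Clusters that failed any of these stayed unnamed, and 8 did. An NK state name needed a mean log2 excess of 0.7 over the other NK-like cells, 3 markers at double level or more and 2 markers among the 12 leading genes. The last condition was added after the clusters had been seen.

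UMIs of NK-like cells were summed per library and expressed as CPM, computed here from the deposited counts. The 11 libraries with at least 100 NK-like cells were used. Library 4 had 8 NK-like cells and library 6 had 93. The level of a gene list is the mean over its members of log2(CPM + 10), relative to the median library, over members of at least 10 CPM in the pooled NK-like cells. The 21 gene lists were fixed before the data were examined. The planned choice of named genes rested on tests. It was replaced, after the lack of a map was known, by a rule of size: the 2 members with the highest level and the 2 with the widest range per list, the 12 genes that stood highest and the 12 that stood lowest in 1 library against the median library among genes of at least 20 CPM, the CALHM family, and 12 genes fixed in advance. Of the genes chosen this way, 1 is not reported here. As planned, immunoglobulin and T cell receptor segments, Gm and Rik models and mitochondrial genes were left out, and genes at over 5 times the NK-like level in another class were named apart. The range step was tested on simulated counts of 5420 genes in NK-like cells: 100 of 100 genes raised 2-fold and 100 of 100 raised 4-fold in 1 library were placed in the right library, and 0 of 5220 unchanged genes had a log2 range of 1 or more. Apart from the raised genes, all simulated libraries shared 1 pooled profile with Poisson counts. The simulation therefore covers counting error only, not free RNA, cluster mix or other differences between libraries.

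Free RNA was read from barcodes of under 100 UMIs. Gene positions come from the GENCODE M21 annotation of GRCm38 (mm10), in which 32158 of the 32285 gene identifiers of the files were found. The alternatives tried were other cell filters, doublet rules, cluster resolutions, class rules, a thinned cell cycle call, free-RNA subtraction and a pseudocount of 1 CPM.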

Results

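Single-cell transcriptomes of mouse NK cell preparations were collected to follow NK cells from culture into the spleens and tumors of mice carrying B16F10 melanoma or E0771 breast carcinoma. The 13 libraries held 544698023 UMIs in all. Library totals ran from 17770645 to 61208754 UMIs with a median of 43590767. After filtering, 91056 cells remained, from 1427 cells in library 6 to 14332 in library 3, with a median of 8015. The median UMI count per cell ran from 2099 in library 13 to 12161 in library 6. Library 4 was of low yield: 11150 of its barcodes had at least 500 UMIs and 200 genes, but 1726 cells remained, and 1381 barcodes were lost to the mitochondrial limit. Library 1 lost 899 barcodes to that limit and kept 4781 cells.

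The design asks how NK cells differ between tumor and spleen, between days 7 and 15, between the tumor models, and before and after injection. The barcodes are not tied to these labels, so those questions are not answered here. The libraries are described side by side under their suffix numbers, without replicates and without tests. Differences between libraries can reflect tissue, day, model, cell preparation or library quality.

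NK-like cells made up 68.4% of all cells (95% interval 68.1 to 68.7), or 62274 cells. They were named from 14 markers, among them the lectin-type receptor genes Klra8, Klre1 and Klrd1, the activating receptor gene Ncr1 and the cytotoxic genes Prf1 and Gzma. Clusters 33, 35 and 36 had 7, 8 and 6 of these markers, and each of the other 10 NK-like clusters had 12 or more. Their share ran from 0.463% in library 4 to 99.3% in library 8, with a median of 76.5%. T cell-like cells, led by Cd3e, Cd3d and Trac, were 13.1% of cells. They made up 71.4% of library 7 (70.5 to 72.4) and 27.5% of library 11 (26.5 to 28.5). B cell-like cells, led by Cd79a and Ms4a1, reached 22.9% in library 11 (22.0 to 23.8) and 14.3% in library 5 (13.6 to 15.0). Library 5 also held 11.9% erythroid-like cells with globin transcripts, 7.95% macrophage-like cells and 5.05% neutrophil-like cells. Any enrichment of NK cells before loading would set such shares.

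Melanoma-like cells carried the pigment cell genes Dct, Pmel, Mlana and Tyrp1. They made up 61.9% of library 4 (59.6 to 64.2) and 68.7% of library 6 (66.2 to 71.1). Library 2 held 90 such cells, and the other 10 libraries held 0. Macrophage-like cells were 22.1% of library 6, 16.3% of library 13 (14.5 to 18.1) and 11.6% of library 4 (10.2 to 13.3). Plasma cell-like and mast cell or basophil-like cells were rare, at 0.233% and 0.0527% of all cells. No cluster was named for an epithelial or mammary carcinoma cell. At Leiden resolution 2, an unnamed cluster had that class as its candidate, as given below.

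**Figure D1:**
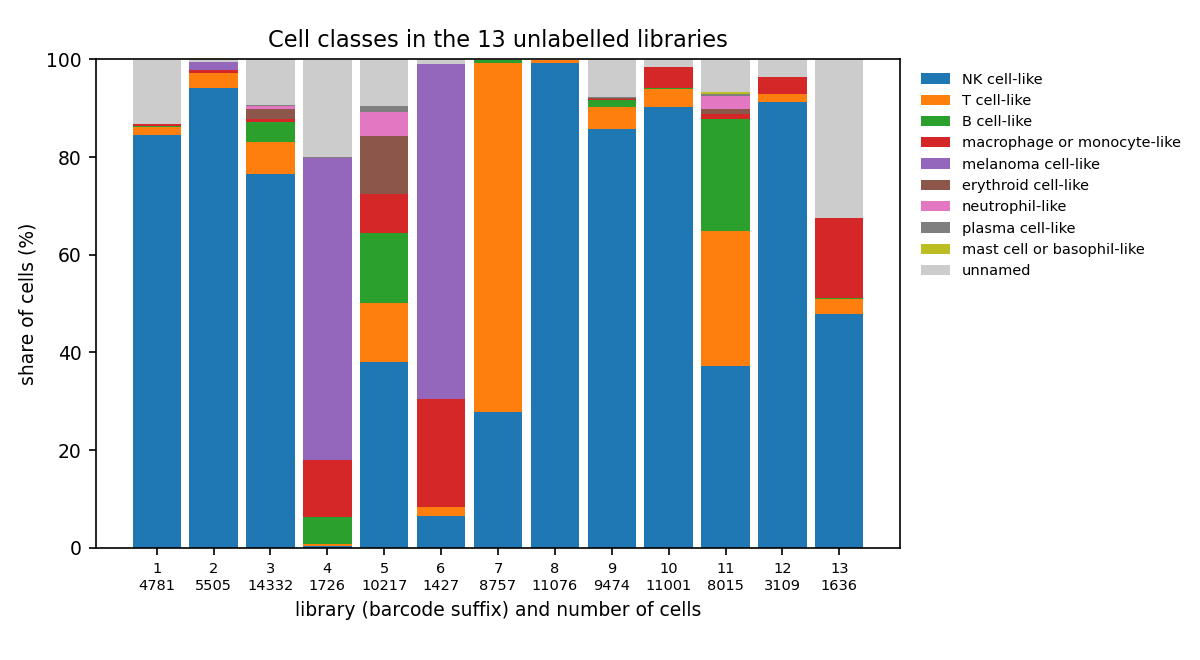
Each bar is 1 library, named by barcode suffix with its number of cells underneath, and the stacked colours give the share of its cells in each class in percent. NK-like cells run from 0.463% in library 4 to 99.3% in library 8, and melanoma-like cells fill most of libraries 4 and 6.

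The 8 unnamed clusters held 5.95% of cells, from 0 in library 8 to 32.5% in library 13. Cluster 5, unnamed for its low UMI count (median 1214), had a median of 7.87% mitochondrial UMIs. Of its 499 cells, 469 lay in library 1. The 1878 cells of cluster 4 had 12 of the 14 NK markers and were led by Cd7, Cd160, Il7r, Cxcr3 and Xcl1, genes known from immature NK cells and type 1 innate lymphoid cells. The T cell receptor gamma segment Tcrg-C4 was also among the leading genes, while Cd3e was at 3.98 CPM. The cluster stayed unnamed because of Batf3, a dendritic cell marker, among its leading genes. It held 677 cells of library 3, 523 of library 9, 261 of library 11, 257 of library 5, 124 of library 1, and 12 or fewer of each other library. Cluster 27 comprised 836 cells with a median of 26148 UMIs, led by Ccl2, Ctsl, Cald1, Sparc, Wfdc2 and Rhox5. Of these, 527 lay in library 13, 173 in library 10 and 98 in library 12. Its best match was the fibroblast list, a name it lost at the finer resolution, and Wfdc2 is a marker of the epithelial list. At resolution 2, a cluster of 760 cells was also led by Ccl2, Ctsl, Cald1, Wfdc2 and Rhox5. Its candidate was the epithelial or mammary carcinoma cell, but with 2 of 12 markers present it stayed unnamed.

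NK-like cells formed 13 clusters. Clusters 0 and 1 carried the mature state, with the terminal maturation genes Cma1, S1pr5, Zeb2 and Klrg1, and held 29.8% of NK-like cells (29.4 to 30.2). This share was 73.5% in library 5, 67.1% in library 9, 62.7% in library 3, 59.5% in library 11 and 38.5% in library 1. Among NK-like cells, cluster 0 was also led by Hbb-bs, Hba-a1, S100a8 and S100a9, transcripts of erythroid cells and neutrophils. At resolution 2, 2684 NK-like cells of library 5 lay in a mature cluster led by these 4 genes. The order of the mature shares is not that of the maturation list. That list was lower in library 5 (0.82) than in libraries 3 (1.19), 11 (1.24), 1 and 9 (1.31 each). The mature share was 0.846% in library 12, 0.135% in library 2, 0.128% in library 13, 0.121% in library 10, 0.0364% in library 8 and 0 of 2439 cells in library 7. Clusters 8 and 15 carried the cytokine or chemokine state. Ccl3, Ccl4, Xcl1 and Nr4a3 led cluster 8, and Ifng, Ccl4, Nr4a1, Cxcl10 and Isg15 were among the leading genes of cluster 15. Their share was 23.9% in library 13 (20.9 to 27.0), 19.7% in library 10 (19.0 to 20.5), 17.5% in library 12 (16.1 to 18.9) and 3.19% or less in each of the other 8 libraries. Cycling clusters 9 and 36, with Top2a, Mki67 and Stmn1, held 10.5% of NK-like cells in library 8 (9.92 to 11.1) and 0.541% in library 2 (0.36 to 0.78). After thinning each cell to 1000 UMIs, the share with at least 3 of the 14 cycling markers ran from 0.792% in library 2 to 9.81% in library 8, against 4.05% and 15.9% at full depth. In B cell-like cells the thinned share was 0.403%.

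Some NK-like clusters belonged almost wholly to 1 library, and such a cluster may be that library and not a cell state. Cluster 35 held 96.8% of the NK-like cells of library 7 (96.1 to 97.5). It had the T cell gene Cd3e at 40.2 CPM, the highest among NK-like clusters, in the library richest in T cell-like cells. It carried a list fixed for NK cells activated in culture, with the granzyme genes Gzmd, Gzme and Gzmf and with Spp1 and Lgals3. At Leiden resolution 2, 866 NK-like cells of library 7 lay in cluster 44, with this name, and 1497 in cluster 45, without a state name. The name of the list does not show where the cells came from. Those 866 cells held 13100918 of the 19025678 NK-like UMIs of library 7, so summed levels there mostly describe them. At this resolution, cluster 44 had 7 of the 14 NK markers, with Ncr1 at 41.4 CPM and Cd3e at 54.0 CPM. Cluster 45 had 13 of the 14, with Ncr1 at 252.2 CPM and Cd3e at 8.56 CPM. Cluster 33 held 89.4% of the NK-like cells of library 8, was led by Igfbp7, Slco4a1 and S100a4, and took no state name. Cluster 20, led by Nr4a2, Pmepa1, Cxcr4 and Vegfa, held 72.4% of library 2 (71.1 to 73.6), 28.5% of library 10, 14.9% of library 13 and 14.8% of library 12. Cluster 19, led among all cells by Xcl1, Rgs1, Rgs16 and Gzmc, held 30.3% of library 10, 24.0% of library 12, 23.6% of library 13 and 11.2% of library 2. Cluster 21, led by the heat shock genes Hspa1a and Hspa1b, held 9.17% of library 2, 6.87% of library 12 and 5.1% of library 13. Cluster 18, led by Serpinb9b and Gzmb, held 30.4% of library 12, 30.2% of library 13 and 17.4% of library 10. Cluster 2, led by Klra4 and Itgax, held 57.1% of library 1, 33.6% of library 11, 33.4% of library 3, 29.2% of library 9 and 19.9% of library 5. Against the other NK-like cells, its first gene was Gm42418. At Leiden resolution 2, 1300 of the 4041 NK-like cells of library 1 lay in a cluster led by Gm42418, AY036118 and Lars2. The mitochondrial gene mt-Nd4l was also among its leading genes. Whether cell quality bears on the levels of library 1 was not tested. Clusters without a state name made up 57.2% of NK-like cells. Without the condition on leading genes, cluster 19 would have taken the interferon state, cluster 33 the resident state and cluster 21 the cytokine state.

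Calhm2, the gene named in the title of the study, encodes a member of the calcium homeostasis modulator family of membrane channel proteins (ENSMUSG00000033033, protein-coding, chromosome 19, 47105353 to 47138294, minus strand, GRCm38). It had 32.7 CPM in pooled NK-like cells (31.9 to 33.4). Per library its level was 65.9 CPM in library 9 (63.0 to 68.9), 61.3 in library 1 (57.7 to 65.0), 55.8 in library 11 (51.2 to 60.6), 55.7 in library 3 (53.1 to 58.4) and 34.6 in library 5 (30.9 to 38.7). It was 15.9 CPM in library 8 (14.8 to 17.1), 13.5 in library 2 (11.9 to 15.3), 10.1 in library 7 (8.71 to 11.6), 10.1 in library 12 (8.3 to 12.3) and 8.86 in library 10 (7.78 to 10.1). Library 13 had 2 Calhm2 UMIs (1.68 CPM, 0.203 to 6.07). Different clusters hold most NK-like cells of these libraries, as given above. Within library 7 at resolution 2, Calhm2 was at 5.88 CPM in cluster 44 (4.64 to 7.35) and 19.7 in cluster 45 (16.2 to 23.7). In the barcodes of under 100 UMIs, Calhm2 was at 17.1 CPM in library 8, 10.1 in library 7 and 9.99 in library 13, at or above the NK-like level there. Among NK-like clusters, Calhm2 was highest in the mature clusters 1 (79.1 CPM, 74.1 to 84.3) and 0 (67.5 CPM, 64.8 to 70.2) and lowest in cluster 15 (5.71 CPM, 4.06 to 7.8). By class, Calhm2 was at 82.2 CPM in mast cell or basophil-like cells (15 UMIs, 46.0 to 135.5), 58.8 CPM in B cell-like cells (54.5 to 63.3), 14.7 in macrophage-like cells (12.8 to 16.9), 9.81 in T cell-like cells (8.93 to 10.7) and 1.83 in melanoma-like cells (1.41 to 2.34). These class levels pool libraries. Of the 11899 T cell-like cells, 6254 lay in library 7, where Calhm2 in NK-like cells was also low (10.1 CPM). Of the 48 mast cell or basophil-like cells, 31 lay in library 11. They had Ncr1 at 405.3 CPM, against 724.0 in NK-like cells, so NK cell RNA may add to their Calhm2. Class and library are therefore not separated here. Calhm2 overlaps Pdcd11 on the opposite strand.

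Calhm6 (ENSMUSG00000046031, chromosome 10, 34126067 to 34127984, minus strand, GRCm38) stood at 34.2 CPM in NK-like cells, from 9.89 CPM in library 8 (9.0 to 10.8), or 0 there after free-RNA subtraction, to 54.5 in library 5 (49.7 to 59.5). In library 8 that subtraction takes out too much, as given below. NK-like cells were not the class with the highest Calhm6 level. It was higher in macrophage-like cells, at 105.9 CPM (100.6 to 111.3), and in T cell-like cells, at 102.9 CPM. As with Calhm2, these class levels pool libraries. In the barcodes of under 100 UMIs, Calhm6 was at 67.0 CPM in library 7 (58.1 to 76.8), above the NK-like level there (39.5, 36.8 to 42.5). In library 8 it was at 14.5 CPM (10.8 to 19.1) against 9.89, with intervals that meet at 10.8. Values of 43.4 in library 10 (36.1 to 51.7) and 42.5 in library 1 (33.8 to 52.8) overlapped the NK-like intervals (33.6 to 38.1 and 34.8 to 40.5). Calhm1, Calhm3 and Calhm4 had 0 UMIs in NK-like cells, which allows up to 0.0137 CPM each. Calhm5 had 1 UMI in NK-like cells and 128 in melanoma-like cells (3.61 CPM, 3.01 to 4.29).

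**Figure D2:**
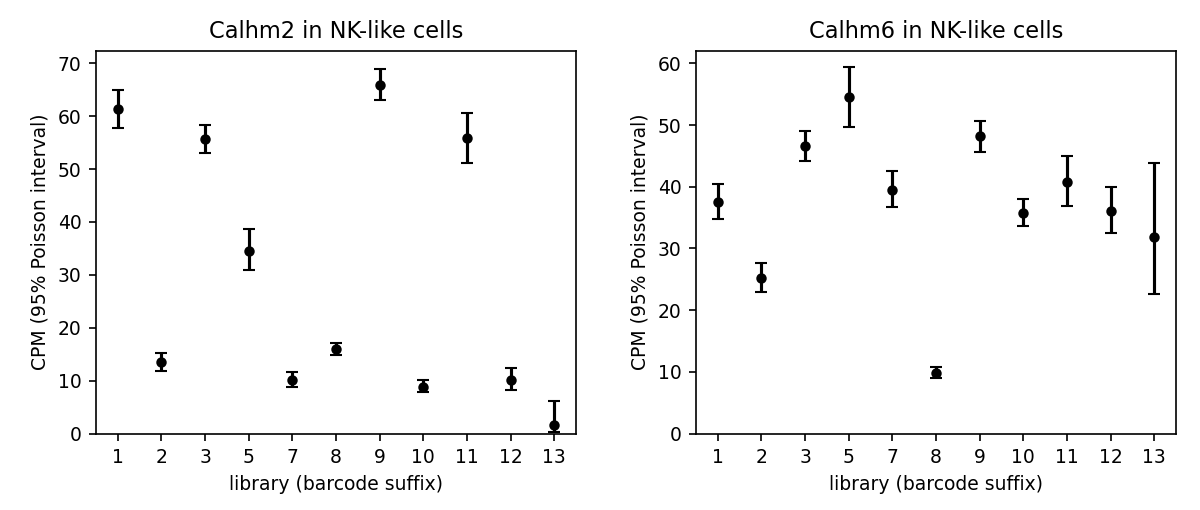
Points give the level of Calhm2 (left) and Calhm6 (right) in the summed NK-like cells of each of the 11 libraries in CPM, and bars the 95% Poisson interval, which covers counting error only. Calhm2 runs from 1.68 CPM in library 13 to 65.9 in library 9, and Calhm6 from 9.89 CPM in library 8 to 54.5 in library 5.

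Among the 12 genes fixed in advance, the NK receptor gene Ncr1 ran from 103.2 CPM in library 7 to 1443.3 in library 9 (median 581.7). As given above, summed levels of library 7 mostly describe its cells in cluster 44 of resolution 2. Prf1, which encodes the pore-forming protein perforin, was at 39.8 CPM in library 8 against a median of 1065.1 and 1856.8 in library 7. Without cells with a T, B or myeloid marker UMI, library 7 had 146.4 CPM of Ncr1 and 1577.2 of Prf1. Granzyme gene Gzmb reached 9274.7 CPM in library 12 and was lowest at 477.3 in library 1. Ifng, which encodes interferon gamma, was at 1303.4 CPM in library 13 and 1.65 in library 8 (median 79.9). The value of library 13 was 260.7 CPM when cells needed 1000 genes and 2000 UMIs, and 3740.7 CPM after free-RNA subtraction. That subtraction also left 0 CPM of Prf1 in library 8. Its free-RNA share rests on markers of B, erythroid and melanoma cells and neutrophils, of which libraries 1, 7, 8, 10, 12 and 13 held 0 to 49 each, so the subtraction is uncertain there. In library 8 it takes out too much: Ifng was lower in NK-like cells (1.65 CPM, 1.3 to 2.07) than the estimated share of 69.5% of free RNA, with 7.55 CPM of Ifng (4.93 to 11.1), would bring in. The maturation receptor gene Klrg1 ran from 3.04 CPM in library 8 to 230.5 in library 9. The transcription factor genes Tcf7 (19.7 to 177.0 CPM), Eomes (145.4 to 510.0), Tbx21 (18.1 to 198.1) and Prdm1 (0.84 to 55.2) had medians of 69.4, 263.5, 84.4 and 29.0 CPM. The lowest Prdm1 value is 1 UMI in library 13 (0.0213 to 4.68 CPM), and 0 when cells needed 1000 genes and 2000 UMIs or after free-RNA subtraction. The lowest Tcf7 value, in library 7, was 6.65 CPM after free-RNA subtraction. The checkpoint receptor genes were low. Pdcd1, which encodes PD-1, was at 37.9 CPM in library 10, 29.4 in library 13, 11.1 in library 12, 7.0 in library 2 and 1.84 or less in the other 7 libraries. Lag3 ran from 1.81 CPM in library 1 to 36.5 in library 10, and Tigit from 0.715 in library 9 to 7.62 in library 10.

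Effector genes differed widely between libraries. The 16 measured cytotoxic effector genes had a median log2 range of 3.97, and 12 of them ranged over 4-fold or more. The list stood highest in library 7 (2.95 on the log2 scale relative to the median library) and lowest in library 1 (-0.3). Gzmc was at 15120 CPM in library 7 against a median of 713.2, and Gzmd at 12871 CPM in library 7 against a median of 1.15. Gzmg was at 14169.4 CPM in library 7 and had 0 UMIs in libraries 1, 5 and 11, which allows up to 0.164 CPM in library 1. Gzmc, Gzmd and Gzmg are similar in sequence, and reads that fit more than 1 of them were not tested. Gzma was lowest in library 8, at 2070.4 CPM, or 1150.1 after free-RNA subtraction, against a median of 14368.4. Chemokine and cytokine genes stood lowest in library 8 (-0.98), next to library 7 (-0.97), and highest in library 13 (1.19). This distance of 2.17 was 3.93 after free-RNA subtraction and 1.65 when cells needed 1000 genes and 2000 UMIs. As given above, the subtraction takes out too much in library 8 and is uncertain in library 13. Ccl4 was at 2419.2 CPM in library 12 and 24.7 in library 8. Ccl5 ran from 1509.5 CPM in library 7 to 23193.6 in library 9.

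Taken as a list, maturation genes were lowest in libraries 8 and 7. The maturation list, with 21 measured genes, stood at 1.31 in libraries 1 and 9, -0.6 in library 7 and -1.17 in library 8. Klf2, a regulator of lymphocyte trafficking, was at 4.34 CPM in library 8 and 9.88 in library 7, against a median of 743.7. Some members went the other way in library 7. Klrg1 was at 164.5 CPM there (median 94.8), Ly6c2 at 373.3 (median 268.5) and Irf8 at 817.5 (median 461.1). Inhibitory receptors and checkpoints were lowest in library 8 (-1.17) and highest in libraries 9 and 12 (0.14 each). Klra7 was at 728.4 CPM in library 9 and 133.6 in library 8, or 32.2 there after free-RNA subtraction. Activating receptors and adaptors ran from -0.76 in library 7 to 0.48 in library 9. Their adaptor gene Fcer1g ran from 2716.6 CPM in library 7 to 4427.5 in library 13, or 11052.2 in library 13 after free-RNA subtraction. The subtraction is uncertain in library 13 and takes out too much in library 8. Chemokine receptor and trafficking genes ran from -1.07 in library 7 to 0.5 in library 1, and the integrin gene Itga4 from 68.7 CPM in library 7 to 1058.3 in library 1.

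Early NK genes stood highest in library 2 (0.91) and lowest in library 7 (-0.25), next to library 9 (-0.23). Emb was at 984.1 CPM in library 2 and 64.3 in library 9. Residency and type 1 innate lymphoid genes were also highest in library 2 (0.74), next to library 10 (0.68), and lowest in library 3 (-0.64), next to library 5 (-0.63). Rgs1 was at 1059.2 CPM in library 2 against a median of 73.6. The TGF-beta response list was at 1.58 in library 2, 1.37 in library 10, 1.32 in library 13, 0.91 in library 12 and -0.38 in library 5. Pmepa1, a target of TGF-beta signalling, was at 325.2 CPM in library 2 against a median of 2.7. It was at 251.1 CPM in library 13, 212.6 in library 10 and 86.1 in library 12. Smad7 was at 433.7 CPM in library 2 against a median of 67.9. Immediate early and dissociation stress genes, which tissue digestion can induce, were at 2.32 in library 2, 1.83 in libraries 10 and 12, 1.8 in library 13 and 0.01 or less in the other 7 libraries. Junb was at 2419.3 CPM in library 2 and 72.9 in library 8. The heat shock list ran from -0.26 in library 9 to 0.93 in library 2, with 0.88 in library 12 and 0.79 in library 13. Hspa1a was at 572.4 CPM in library 2, 184.6 in library 12 and 141.1 in library 13, and had 0 UMIs in libraries 1, 5 and 9.

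The type I interferon list stood at 1.53 in library 12, 1.51 in library 13 and 1.44 in library 10, and was lowest in library 8 (-0.88). The distance between libraries 12 and 8, 2.41, was 3.71 with a pseudocount of 1 CPM. Isg15 was at 502.2 CPM in library 13 against a median of 37.0, 224.2 CPM there when cells needed 1000 genes and 2000 UMIs, and 0 after free-RNA subtraction. The subtraction is uncertain in library 13, where it also took Hsp90ab1 from 3036.8 CPM to 0. Ifi27l2a was at 307.7 CPM in library 12 and 0.176 in library 8. The interferon gamma and antigen presentation list ran from -0.78 in library 8 to 0.52 in library 10, with the class I gene H2-D1 at 5141 CPM in library 10 and 1551.6 in library 7. The IL-2 and STAT5 list ran from -0.28 in library 3, next to -0.27 in library 9, to 0.91 in library 13, next to 0.87 in library 10. In library 13, Cd83 was at 187.3 CPM against a median of 3.95, or 457.6 CPM after free-RNA subtraction.

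Glycolysis, hypoxia and sterol synthesis genes were highest in library 7. Glycolysis genes stood at 1.22 in library 7 and -0.53 in library 1, with Pgk1 at 1746.3 CPM against a median of 241.0. Hypoxia response genes stood at 0.88 in library 7 and -0.19 in library 5. Library 7 led by little here, with 0.8 in library 2, 0.71 in library 10, 0.59 in library 13 and 0.55 in library 12. Mif was at 686.3 CPM in library 7, and Vegfa was highest in library 2 (215.4 CPM). Sterol and lipid synthesis genes were at 1.36 in library 7 and -0.21 in library 13, with Fdps at 307.5 CPM against a median of 17.8. Oxidative phosphorylation genes differed less between libraries. The list ran from -0.3 in library 7 to 0.37 in library 5, and 2 of its 41 genes ranged over 4-fold or more. The cell cycle list ran from -0.42 in library 1, next to -0.41 in libraries 2 and 7, to 1.03 in library 8. This distance of 1.45 was 0.23 without the cycling clusters and -0.45 after free-RNA subtraction, which put library 8 below library 1. That subtraction takes out too much in library 8, so the reversal is not reliable. The thinned cycling share was highest in library 8 (9.81%). Ube2c was at 180.1 CPM in library 8, or 9.43 CPM without the cycling clusters and 16.2 CPM after free-RNA subtraction.

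**Figure D3:**
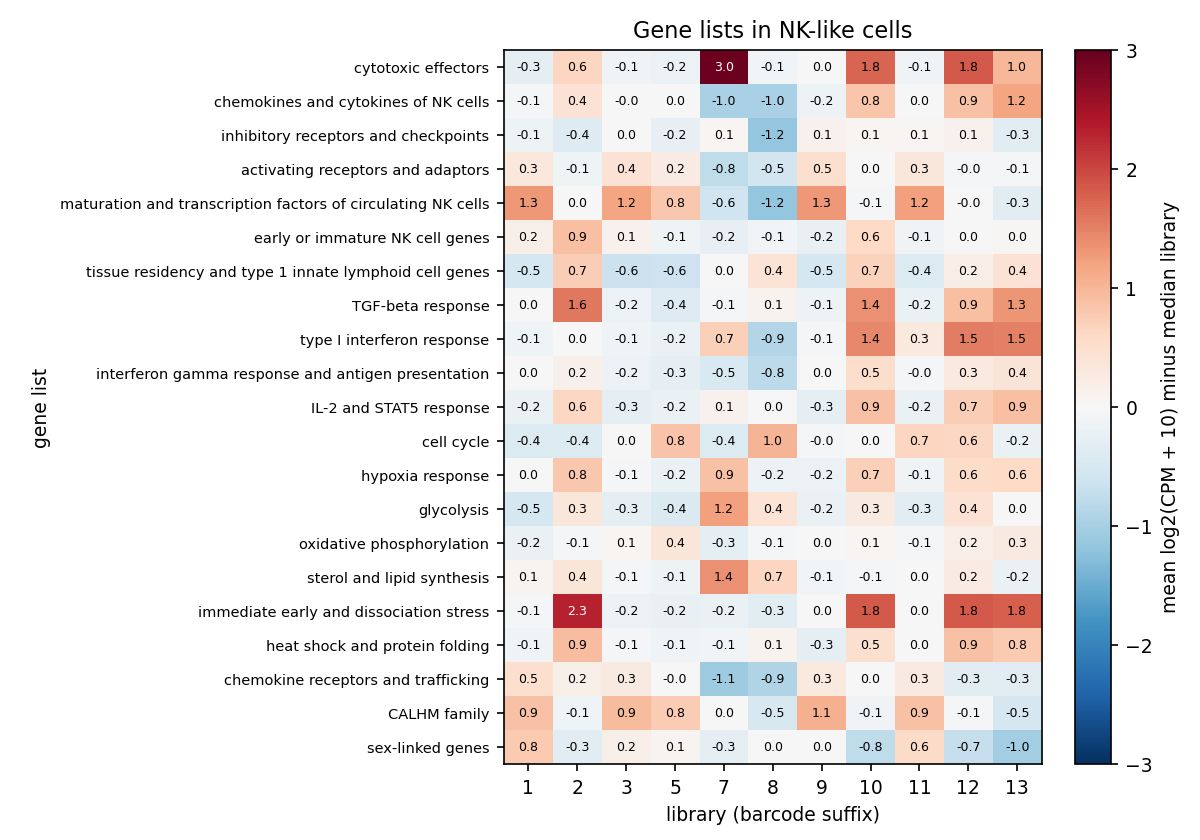
Rows are the 21 gene lists and columns the 11 libraries. Colour and printed values give the mean log2(CPM + 10) of each list in NK-like cells minus that of the median library. Cytotoxic effectors reach 2.95 in library 7, and the immediate early list 2.32 in library 2.

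Among 5280 genes of at least 20 CPM, the median log2 range over the 11 libraries was 1.2, and 788 genes (14.9%) ranged over 4-fold or more. Of the 12 genes that stood highest in 1 library against the median, Gzmg, Gzmd, Gzme, Gzmf, Gzmc and Spp1 were highest in library 7. Igfbp7 (1130 CPM against a median of 0.11), S100a4 (3806.9 against 126.0) and Slco4a1 (247.8 against 1.35, and 0 after free-RNA subtraction) were highest in library 8, and Hspa1a, Hspa1b and Pmepa1 in library 2. The 0 of Slco4a1 is not reliable, since the subtraction takes out too much in library 8. Among the 12 that stood lowest, Klf2, Prf1, Ccl4, Ly6c2, Serpinb9b, Cma1, Irf8 and Slamf7 were lowest in library 8, Ccl5 and Itga4 in library 7, and Gzmc in library 1. Gzmc was not low in library 1 alone: it was at 2.74 CPM there, 3.96 in library 11, 4.28 in library 5, 4.78 in library 3 and 8.96 in library 9. Genes named apart as possibly carried over from other cells include Ifitm1 (3844.1 CPM in library 7, and 6019 CPM in mast cell or basophil-like cells) and Mt1 (1761.8 CPM in library 7, and 3176.5 CPM in melanoma-like cells). That rule uses class levels over all libraries. Library 7 itself held 1 mast cell or basophil-like cell and 0 melanoma-like cells, which argues against these 2 classes of that library as the sources. Both genes were among the leading genes of NK-like cluster 35. Ifitm1 was also among those of T cell-like cluster 30, with 99.3% of its cells in library 7. The depth allowed these values to be told apart from counting error: a level of 100 CPM had an interval of 97.1 to 102.9 in library 8 and 82.8 to 119.6 in library 13, the shallowest.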

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

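Apart from the Poisson test of C1q and the free-RNA test of Calhm2, the tests in this part were chosen only after the result was seen. No library is tied to a group, so no biological explanation was tested.

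Melanoma transcripts appeared where no melanoma-like cell was found. In the 10 libraries without melanoma-like cells, barcodes of under 100 UMIs, which lie outside the cells of the main measurement, held 3089 Dct UMIs. The free-RNA profile comes from the same barcodes and includes these UMIs. Per library this was 33.8 to 267.6 CPM with a median of 101.2, above the limit that a count of 0 allows. Of these UMIs, 54.4% sat on a barcode sequence that belongs to 1 of the 2139 melanoma-like cells of libraries 2, 4 and 6, and 0.68% on a sequence of 1 of the 6518 other cells of those libraries. Per barcode sequence this is a ratio of 243.8, which argues against melanoma RNA free in each suspension as the whole source, since such RNA would fall on barcodes at random. A candidate explanation for at least this part is swapping of sample indices between libraries sequenced together.

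Cluster 7 holds 572 barcodes with NK transcripts and macrophage genes such as C1qa, Hmox1 and Vcam1. Judged by 8 macrophage markers, macrophage RNA made up 8.06% of these barcodes in the median of 5 libraries (4.78 to 14.8%). Adding back barcodes removed as doublets that lay nearest to cluster 7 gave 668 barcodes and 9.99%. Removed barcodes nearest to other clusters stayed out, so this step cannot tell whether such doublets were removed. The median UMI count of the 572 kept barcodes was 0.72 to 1.27 times that of mature NK-like cells of the same library (median 1.22). Both values were highest in library 5, at 14.8% (17.5% with the added barcodes) and 1.27. For the kept barcodes, the share and the UMI counts argue against doublets of an NK cell and a whole macrophage. Evenly spread free RNA also does not account for them, since 377 barcodes of the NK-like cells and cluster 7 had 3 or more C1q UMIs where a Poisson law gave 63.8 (ratio 5.91, 5.33 to 6.54). Macrophage fragments attached to NK cells, and a macrophage-like program in NK cells, stay open and were not tested.

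Calhm2 in NK-like cells differed 7.43-fold between the highest and lowest of the 10 libraries with at least 10 Calhm2 UMIs. After subtraction of free RNA the difference was 6.83-fold, which argues against free RNA as the cause. The estimated free-RNA share was 3.34 to 8.56% in libraries 1, 2, 3, 5, 9 and 11, 19.7% in library 12, 31.2% in library 7, 40.1% in library 10, 69.5% in library 8 and 88.6% in library 13. It is uncertain in libraries 1, 7, 8, 10, 12 and 13, which held 0 to 49 cells of the classes whose markers it rests on, and too high in library 8, where the 1.65 CPM of Ifng in NK-like cells lie below what 69.5% of free RNA with 7.55 CPM would bring in. In library 7, however, free RNA and NK-like cells had the same Calhm2 level (10.1 CPM each), so no share would raise that library towards library 9, where free RNA was lower (36.6 CPM) than NK-like cells (65.9 CPM). Whether the mix of clusters accounts for the difference between the highest library (library 9) and the lowest (library 10) cannot be told apart from other causes, since 0 clusters at Leiden resolution 2 held 100 or more cells of both. In cycling cluster 9 of resolution 1, Calhm2 was at 35.7 CPM in library 9 (27.3 to 45.9) and 7.52 CPM in library 10 (3.75 to 13.5), which argues against the mix of resolution 1 clusters as the whole cause. At resolution 2, however, the cycling cells of these libraries lay in separate clusters, 10 (171 cells of library 9) and 27 (205 cells of library 10), so a finer mix stays open. In cluster 2 of resolution 1, with 100 or more cells in each of 5 libraries, Calhm2 was at 56.6 CPM in library 1, 51.7 in library 9, 49.9 in library 11 and 47.0 in library 3, against 20.1 in library 5 (14.8 to 26.6). At resolution 2, library 5 was below libraries 1, 3, 9 and 11 in cluster 2 (18.1 CPM against 40.4 to 47.2) and cluster 3 (44.8 against 64.7 to 88.2), but level with them in cluster 1 (62.2 CPM, 39.4 to 93.3, against 61.6 to 72.8). Tissue, day, tumor model, culture, genotype of the NK cells and library preparation stay open.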

How the results depend on the processing

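The settings called added here were chosen after seeing the data. No paired analysis was possible because no barcode is tied to a sample, so no mouse or replicate number can be matched. For the same reason the settings chosen beforehand for the tests of tissue, day, tumor model, culture and gene lists were not run (size factors, DESeq2, count filters, covariates, leaving out samples, camera with an estimated correlation, fry, pseudocounts and thresholds against culture).

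The NK-like share of all cells, 68.4%, was 62.8% with 200 genes and 500 UMIs (planned), and under added settings 68.8% with the automatic doublet threshold, 72.2% at 5% mitochondrial UMIs, 69.0% with 1000 genes and 2000 UMIs, 68.8% at Leiden resolution 2 and 70.5% with cluster 4 as NK-like. In the median library it was 76.5%, and 67.2%, 78.7%, 73.5% and 81.2% with 200 genes, 5% mitochondrial, 1000 genes and cluster 4. The T cell-like share, 13.1%, became 11.8%, 11.3% and 13.8% with 200 genes, 5% mitochondrial and 1000 genes. The B cell-like share, 4.64%, became 4.24%, 4.49%, 3.13%, 3.31% and 4.8% with 200 genes, the automatic threshold, 5% mitochondrial, 1000 genes and resolution 2. The macrophage-like share, 2.67%, was 3.37% at resolution 2. The melanoma-like share, 2.35%, was 2.17% with doublets kept (planned), 2.18% with the automatic threshold and 2.05% at 5% mitochondrial. At resolution 2 (planned) the mature share of NK-like cells was 34.2% in place of 29.8%, the cytokine or chemokine share 6.05% in place of 5.34%, the cycling share 4.11% in place of 3.77%, and that of the activation list 1.39% in place of 3.84%. Resolution 2 also gave state names that resolution 1 lacks: interferon-stimulated (clusters of 227 and 1595 cells) and resident (831 cells). Counting cluster 4 gave a mature share of 28.9%. Dropping the condition on leading genes gave a cytokine or chemokine share of 6.74%. A cycling call from markers gave 3.84% in thinned cells (planned) and 7.69% at full depth. The other values of these shares, and the thinned cycling share, stayed within the counting interval of the reported value. The causes were not tested.

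Among gene lists, the distance between the reported extreme libraries moved by at most 0.07 with doublets kept and at 5% mitochondrial, 0.12 at resolution 2, 0.17 without cells with a T, B or myeloid marker UMI, 0.28 with cluster 4, 0.53 with 1000 genes, 1.22 without cycling clusters, 1.3 with a pseudocount of 1 CPM and 1.9 with free-RNA subtraction (log2). The same libraries were lowest and highest in 20 of 21 lists with doublets kept, at 5% mitochondrial and at resolution 2, in 19 with cluster 4, in 16 without cycling clusters, without cells with a marker UMI and with a pseudocount of 1 CPM, in 13 with 1000 genes and in 7 with free-RNA subtraction. With a pseudocount of 1 CPM the distance moved most in 5 lists, from 2.41 to 3.71 for type I interferon, 1.59 to 2.61 for the CALHM family, 2.49 to 3.44 for maturation, 3.25 to 4.19 for cytotoxic effectors and 2.66 to 3.43 for immediate early genes. Under free-RNA subtraction it went from 2.17 to 3.93 for chemokines and cytokines, 1.57 to 2.84 for sterol synthesis, 1.3 to 2.25 for interferon gamma and antigen presentation, 2.66 to 3.6 for immediate early genes, 1.19 to 1.85 for IL-2 and STAT5, 1.31 to 1.9 for inhibitory receptors, 1.16 to 1.74 for early NK genes and 2.49 to 3.0 for maturation. In library 8 it left 0 CPM of Calhm6, Prf1, Ifng, Klrg1, Klf2, Ccl4, Junb, Irf8 and Ifi27l2a. These zeros reflect subtraction of too much, since the Ifng level of NK-like cells there (1.65 CPM) lies below what the estimated share of 69.5% of free RNA (7.55 CPM of Ifng) would bring in. The subtraction rests on markers of B, erythroid and melanoma cells and neutrophils, of which libraries 1, 7, 8, 10, 12 and 13 held 0 to 49 each. In library 13, with an estimated share of 88.6%, it left 0 CPM of Hsp90ab1, Isg15, Cycs and Higd1a. These stood at 3036.8, 502.2, 412.3 and 267.9 CPM before subtraction, so the estimate is doubtful there too. Depth limits library 13 most, with 784 NK-like cells.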

Other observations

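Sex-linked and relatedness measures were not part of any comparison. Xist, the transcript of the inactive X chromosome, was found in 68.1% of NK-like cells (628.8 CPM, median 2792 UMIs) and in 1.36% of melanoma-like cells (1.47 CPM, median 14361 UMIs), which were sequenced more deeply. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 5 UMIs among 402119025 in all cells, and 0 in melanoma-like cells. In the list of sex-linked genes, NK-like cells of library 1 stood highest (0.79) and those of library 13 lowest (-1.04).

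Cluster 11 stayed unnamed and held 1099 cells led by the granule genes Prtn3, Elane, Mpo and Ctsg, known from immature myeloid cells. Of these, 469 lay in library 5, 361 in library 3, 182 in library 11 and 61 in library 9. Library 8 was the most uniform, with 0 unnamed cells of 11076, which allows a share of up to 0.0333% at the upper bound of the exact interval.

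Over 5431 genes, the correlation of log2 levels in NK-like cells was computed for each pair of the 11 libraries. It is across genes, which are not independent replicates. The closest library was library 9 for library 3 (r = 0.991), library 3 for libraries 9 (0.991), 11 (0.99) and 5 (0.98), library 11 for library 1 (0.967), library 12 for library 10 (0.986), and library 10 for libraries 12 (0.986), 13 (0.98) and 2 (0.974). Libraries 7 and 8 stood apart from the rest, with closest values of 0.891 (library 12) and 0.841 (library 5).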
